A study of Mus musculus with 384 samples.

How the data were processed

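The series holds 384 sorted mouse meningeal wells, 96 on each of 4 plates (aged S1, aged S2, young S1, young S2). Per the labels, cells were sorted as living CD45-negative cells positive for CD31, podoplanin and Lyve1, and each age is a pool of 5 male mice. Library preparation put a well barcode on the oligo-dT primer, and no molecular identifier is described. The deposited tables hold read counts per gene symbol, 1 column per well and 40324 genes, which the authors made, per the submitters' processing notes, with STAR 2.5.1a, Subread and featureCounts 1.4.6-p5 on mm10. The annotation release, strand setting and treatment of reads with several matches are not given in the sources used here, and the values are whole numbers with no normalisation. Coordinates are those of the GENCODE vM21 annotation (GRCm38, the same assembly as mm10), matched by symbol for 40247 genes; Nnt had no unique match.

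Wells with at least 10000 counts and 500 genes were kept, which all 384 did, and 0 pairs of wells had identical counts. Analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Wells were clustered on log counts per 10000, with 2000 highly variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.5. The design asked for clusters called lymphatic-like, by at least 3 lymphatic markers among a cluster's top 10 genes by fold, a threshold set after the data had been seen. The 5 clusters held at most 1, so the fallback of the design applied and all 384 wells were used. The largest cluster (180 wells) drew 49, 41, 46 and 44 wells from aged S1, aged S2, young S1 and young S2, while 3 clusters of shallow wells (median counts per well 57841, 104708 and 62957) came almost wholly from 1 plate each, with 24 of 25, 53 of 54 and 41 of 41 wells.

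Counts were summed over the wells of each age and of each plate and scaled to CPM, the usual scaling by the total of the pool or plate, with exact Poisson 95% intervals. Log2 ratios, aged over young, used a pseudocount of 1 CPM. A ratio was also taken for each of the 4 combinations of an aged and a young plate. Because the labels give 1 pool of mice per age, no test was made. The rule of size asked for at least 50 CPM and a count in at least 20% of wells in the higher age, a log2 ratio of at least 1 in size, the same sign of ratio and of the difference in share of wells in all 4 combinations, and no well with over 25% of the higher age's counts of the gene. Shares of wells have exact Clopper-Pearson intervals, before and after thinning each well to 94000 counts, which left out 36 aged and 38 young wells; thinned wells had a median of 2598 (aged) and 2542.5 (young) genes. A count of 0 allows up to 3 counts.

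The design, the rule of size, the gene lists and the rule for named genes were fixed before the data were examined. The named genes were the 12 higher and 12 lower genes past the rule of size with the largest smallest ratio over the 4 plate combinations, leaving out clone-like symbols (3 of the 247 genes). Sort markers and genes of interest were always named: Prox1, Lyve1, Pdpn, Pecam1, Ptprc, Flt4, Ccl21a, Cdh5, Cldn5, Irf1, B2m, H2-K1, Cd74, Ifngr1, Ifngr2, Nnt and Xist. For each list, up to 4 members past the rule were named, or else the most highly expressed one. There were 24 gene lists: interferon gamma response, type I interferon response, interferon receptors and kinases, MHC class I, MHC class II, adherens junction, tight junction, lymphatic identity, valve and collecting vessel, leukocyte trafficking, NF-kB targets, extracellular matrix, immediate early and dissociation stress, unfolded protein response, mitochondrially encoded and nuclear oxidative phosphorylation, ribosomal proteins, senescence, cell cycle, antioxidant defence, circadian clock, lipid handling, substrain and sex. There were 12 marker lists: lymphatic endothelium, blood endothelium, fibroblast, mural, macrophage, T or NK cell, B cell, neutrophil, mast cell, erythroid, glia or neuron, and bone or cartilage. Members with at least 5 CPM in either age were measured, and each median was placed among those of 10000 random lists matched in 20 bins of expression. Random members were drawn independently, whereas members of a list can be high in the same few wells. An extreme percentile can therefore arise from a few wells, and it describes these pools without being a test. A list counted as called when its percentile lay beyond 2.5 or 97.5 and its median had 1 sign in all 4 combinations, a definition set after the data had been seen. Lists share members, for example Tap1, Psmb8 and Psmb9 (interferon gamma and MHC class I) and Vcam1 and Icam1 (NF-kB and leukocyte trafficking).

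Some definitions were set after the data had been seen, and that of carrying a gene was revised: deep wells (at least 300000 counts, 75 on aged S1, 50 on aged S2, 87 on young S1 and 57 on young S2), carrying a gene (at least 100 CPM and 0.2% of the plate's counts), and a well of a class (3 or more of its markers carried). Spill between wells was estimated from genes with at least 2000 counts on a plate and 80% of them in 1 well. Alternatives covered filters on wells, scaling (edgeR TMM factors 0.989 and 1.01, or totals without mitochondrial and ribosomal protein genes), equal weight per well, thinning, expression minimum, fold, pseudocount, the limit on a single well, clustering settings, and leaving out each plate; 3 were added after the data had been seen (deep wells alone, leaving out the 18 deep wells of another class, and leaving out well A7 of aged S2). The scaling alternatives moved the median log2 ratio of the 4052 genes by at most 0.0306. The comparison was tested on simulated data, in which 50 genes each were set to 0.25, 0.5, 2 and 4 times their level: median log2 ratios found were -2.05, -1.01, 0.98 and 1.93, 50 of 50 had the right sign each time, and 35, 9, 8 and 25 passed the rule of size. A low number past the rule thus does not exclude 2-fold differences. The simulated wells were drawn from 1 mean profile, with no difference between plates and no spill. The signs recovered therefore say nothing on directions where plates differ. Doublets were not called; leaving out the 5% of wells with most genes stood in for it. All explanation tests in the closing text were set after the results were seen.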

Results

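RNA was counted in 384 wells, each sorted from mouse meninges, the membranes around the brain, with a gate for living cells that lacked the leukocyte protein CD45 and carried CD31, podoplanin and Lyve1, surface proteins used together to isolate lymphatic endothelium. The aged pool came from 5 males of 20 to 24 months, and the young pool from 5 males of 2 to 3 months. Each pool filled 2 plates of 96 wells, called S1 and S2. The aged mice were C57BL/6NCRL and the young mice C57BL/6J, so age and substrain cannot be told apart. No mouse is named for any well, which leaves 1 sample per age: no p-value is given, and wells and plates are not replicates. The plates held 77696614 (aged S1), 114409656 (aged S2), 106715771 (young S1) and 91164702 (young S2) counts, with 13478 to 7985189 counts per well. Median counts per well were 795370, 596038, 1077010 and 661442 in the same order, and a well had a median of 5013 genes with a count.

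The wells carried the RNA of vascular endothelium with little of the lymphatic program. Vwf, which encodes the clotting protein von Willebrand factor, stood at 3006 CPM (counts scaled to an equal total per pool) in the aged pool and 3101 in the young pool, Plvap, which encodes the diaphragm protein of fenestrated vessels, at 2382 and 3602, and Emcn, a sialomucin of capillaries and veins, at 1575 and 1625. Prox1, the transcription factor that sets lymphatic identity, had 17 aged and 19 young counts in all, or 0.0885 (95% exact Poisson interval 0.0516 to 0.142) and 0.0960 (0.0578 to 0.1499) CPM. Ccl21a, the chemokine by which lymphatic vessels attract dendritic cells, had 17 counts in the aged pool and 0 in the young pool, which allows up to 0.0152 CPM there, and its copies Ccl21b and Ccl21c had 0 in both. Of the genes for the 3 sorted proteins, Pecam1 (CD31) stood at 810.7 and 810.6 CPM, Lyve1 at 174.7 and 190.1, and Pdpn (podoplanin) at 11.07 and 10.99. Not all lymphatic markers were low: Nrp2 lay above Lyve1 and Flt4 above Pdpn in both pools, with levels given further on. Intervals and limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Plvap, Emcn, Ccl21b and Ccl21c, and the genes so marked further on, were chosen after their values were seen.

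Well by well, 218 of the 269 wells with at least 300000 counts (81.04%, 95% Clopper-Pearson interval 75.8% to 85.5%) carried 3 or more of the 9 blood endothelial markers, and 6 (2.23%, 0.823% to 4.79%) carried 3 or more of the 11 lymphatic markers. A well was said to carry a gene if it had at least 100 CPM of it and at least 0.2% of the plate's counts of it, a definition set after the data had been seen. By age, blood endothelial markers were carried at this number by 82.4% of such aged wells (74.6% to 88.6%) and 79.9% of such young wells (72.4% to 86.1%), and lymphatic markers by 3.20% (4 wells) and 1.39% (2 wells). Lyve1 was carried by 18 aged and 21 young wells, unevenly over the plates (16 on aged S1, 2 on aged S2, 17 on young S1 and 4 on young S2). Of these 39 wells, 37 carried 3 or more blood endothelial markers and 5 carried 3 or more lymphatic markers. Prox1 was carried by 0 wells, which allows up to 1.12% of the 269. In the unthinned counts Prox1 had a count in 4.69% of aged wells and 6.77% of young wells, and after thinning each well to 94000 counts in 0.641% and 0.649%.

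**Figure D1:**
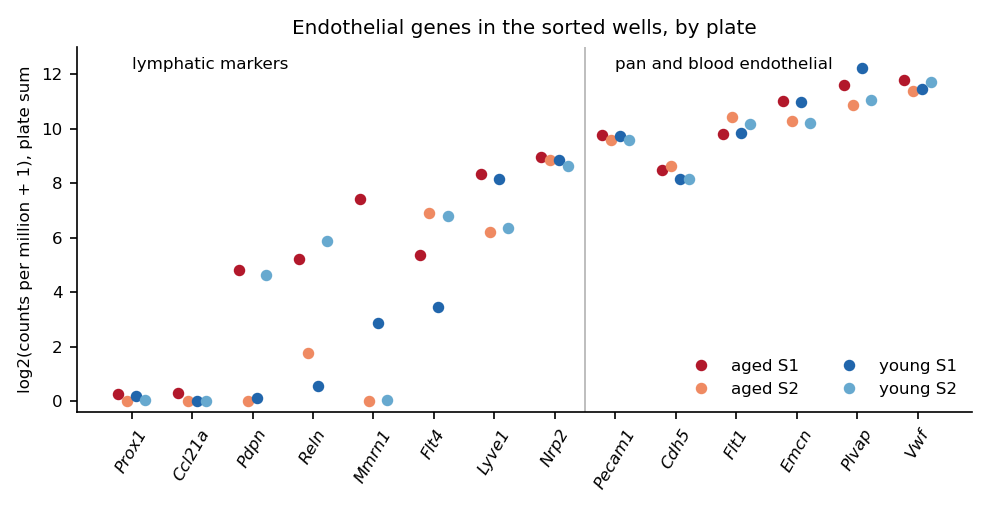
Level of endothelial genes (log2 of CPM plus 1) in the counts summed over each of the 4 plates, 1 point per plate. Pecam1, Vwf and Plvap lie far above Prox1 on each plate, while Lyve1 runs from 73.4 CPM on aged S2 to 324 on aged S1.

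A low count of a gene in a well is not evidence that the cell expressed it. Csf1r, the receptor of the macrophage growth factor, had 19130 counts on young S2, of which 17803 lay in 1 well, yet 71 wells of that plate had a count of it. The other plates held 1, 6 and 0 counts of Csf1r, a gene singled out after its values were seen. Per well, such spill amounted to a median of 0.0573% to 0.0793% of a plate's reads of a gene. Its 95th percentile was 0.424% on aged S1, 0.147% on aged S2, 0.263% on young S1 and 0.197% on young S2. On the S1 plates this lies above the 0.2% asked of a carried gene, so some wells there may carry a gene through spill. As an upper estimate, which includes real expression, it accounted for 5.17% to 6.29% of the counts in wells with at least 300000 counts, and for 52.7% to 92.98% in wells with under 100000. Shares of wells with a count are therefore given beside the numbers of wells that carry a gene.

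Aged against young compares pools that differ in both age and substrain, over all sorted wells, some of which carried markers of other cell classes. Of 7 measured genes for antigen presentation on MHC class II, 6 were higher in the aged pool on each pair of plates, whereas the medians of the interferon lists rested on 1 aged plate (S1). Of 4052 genes with at least 50 CPM in either pool, 247 (6.10%) passed a rule of size, which asks for a 2-fold difference with the same direction in all 4 combinations of an aged and a young plate, and 46.96% of the 247 were higher in the aged pool. Those higher had log2 ratios of 1.01 to 5.43 (median 1.60), and those lower of -5.89 to -1.002 (median -1.63). By the same rule the S1 and S2 plates differed more than the ages did, with 510 genes (12.5%, of which 416 were higher on S1). Between mixed pairs of aged and young plates, 4.43% of genes passed, which is fewer than between the ages. With each well thinned to 1 depth, 289 genes passed and 62.98% were higher in the aged pool. Without 1 plate, which leaves 2 combinations to satisfy, the genes and the share higher were 728 and 16.6% (aged S1), 494 and 57.5% (aged S2), 399 and 81.95% (young S1) or 591 and 34.3% (young S2). Across the 4052 genes, which are not independent replicates, the log2 ratio within S1 plates and that within S2 plates had a Pearson r of 0.208 and a Spearman rho of 0.184. Of 498 genes at least 2-fold apart within both, 351 (70.5%) had the same direction.

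Among the 12 named genes higher in the aged pool, 5 are members of the lists for type I interferon (Ifi44, Ifih1) or MHC class II (Cd74, H2-Ab1, H2-Eb1). Of the 12, 1 still passed the rule of size without aged S1, 8 without aged S2, 6 without the 5% of wells with most genes and 7 without wells with a count of Ptprc. Ifi44, an interferon-induced gene (GRCm38 3:151730922-151749960), stood at 104.5 CPM in the aged pool (103.1 to 105.95) and 1.44 in the young pool (1.28 to 1.62), a log2 ratio of 5.43 (4.85 to 6.71 over the 4 plate combinations). Samhd1, a nucleotide hydrolase that restricts retroviruses, stood at 105.8 and 7.81 (3.60, 2.51 to 5.44), and Ifih1, the cytoplasmic sensor of long double-stranded RNA, at 53.5 and 6.63 (2.84, 2.09 to 4.03). Besides Samhd1, the others were Hivep1 (log2 3.03), a zinc finger transcription factor, Prrc1 (2.77), Dnajc18 (2.65), Nsmce2 (2.56), a SUMO ligase of the SMC5/6 complex, Mrpl38 (2.38), of the mitochondrial ribosome, and Fmnl2 (2.35), a formin that elongates actin filaments. Ifi44 was carried by 14 aged wells and 1 young well, Samhd1 by 12 and 4, and Hivep1 by 8 and 2. On aged S2, wells B8, C2 and E12, picked out after their values were seen, had 2593, 2332 and 2115 CPM of Ifi44. The next highest well there with at least 300000 counts had 36.97, so the level of that plate rests on few wells. After thinning, Ifi44 had a count in 37.2% of aged and 2.60% of young wells (73.96% and 16.1% before).

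Of the 12 named genes lower in the aged pool, 0 still passed the rule of size without young S1, 8 without young S2 and 9 without wells with a count of Ptprc. Pepd lay furthest below 0. This dipeptidase, which frees proline from collagen fragments (GRCm38 7:34912379-35044708), stood at 0.406 CPM in the aged pool (0.321 to 0.507) and 82.2 in the young pool (80.98 to 83.5), a log2 ratio of -5.89 (-6.36 to -5.37). Cyp4f13, a fatty acid hydroxylase, followed at 0.213 and 50.6 (-5.41), then Mcoln1, the calcium channel of the lysosome, at 0.468 and 56.5 (-5.29), and Brf1, a subunit of the RNA polymerase III initiation factor, at 0.489 and 55.02 (-5.23). Atp6v0e2, of the proton pump that acidifies lysosomes (-4.79), Mad2l1bp, which silences the spindle checkpoint (-4.52), Kin (-4.28), Mrps23, of the mitochondrial ribosome (-4.16), and Ccdc88a, the actin-binding protein girdin (-4.03), came next. The last were Inpp5d, the phosphatase SHIP1 (-3.36), Ap4s1, of the AP-4 adaptor (-3.33), and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain (-3.22). Pepd was carried by 0 aged wells (a limit of 2.40% of those with at least 300000 counts) and 13 young wells, and after thinning had a count in 2.56% of aged and 31.2% of young wells (13.02% and 67.2% before). Among the lower genes were 6 for the mitochondrial ribosome, named after their values were seen: Mrpl15, Mrpl42, Mrpl46, Mrpl49, Mrps22 and Mrps23. The higher genes held 3 others.

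MHC class II antigen presentation, by which cells show peptides to CD4 T cells, had the highest median of the gene lists with at least 5 measured members. Of 7 measured members, 6 were higher in the aged pool in all 4 plate combinations and 1, Ctss, was lower. The median log2 ratio was 3.29, above all of 10000 random lists of like expression (percentile 100.0). That percentile is no test, since members of a list can be high in the same few wells. Mural markers also reached 100.0, with 3 or more carried by 7 aged wells and 1 young well. The class II median was 3.35 within S1 plates and 4.76 within S2 plates, or 4.13 there without well A7 of aged S2. That well held 43.8% of its plate's counts of Cd74, 35.7% of those of H2-Ab1, 44.6% of those of H2-Aa and 53.5% of those of H2-Eb1. Cd74, the invariant chain that guides class II molecules (GRCm38 18:60803848-60812652), stood at 442.9 CPM in the aged pool (439.9 to 445.9) and 34.4 in the young pool (33.6 to 35.2). Its log2 ratio was 3.65, with 2.40 to 4.80 over the plate combinations. H2-Ab1, the beta chain of I-A, stood at 264.8 and 26.2 (3.29, 2.48 to 5.10), and H2-Eb1, the beta chain of I-E, at 129.1 and 10.3 (3.52, 1.97 to 7.65). H2-Aa (2.77), H2-DMa (5.99) and H2-DMb1 (2.98), which missed the rule of size, and Ctss (-5.24), the protease that trims the invariant chain, were named after their values were seen. Ctss stood at 0.0364 CPM in the aged pool and 38.1 in the young pool.

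Among wells with at least 300000 counts, Cd74 was carried by 39 aged wells (31.2%) and 6 young wells (4.17%), with 32 of the aged wells on S1 and 7 on S2, and 4 and 2 of the young wells. Of those 39 aged wells, 35 carried 3 or more blood endothelial markers, 26 carried Pecam1, and 2 (5.13%, 0.627% to 17.3%) carried 3 or more markers of an immune class. Well A7 of aged S2, looked at after its values were seen, had the most Cd74 of any well (14949 CPM), carried 7 of the 10 macrophage markers and 0 blood endothelial markers, and had 0 counts of Ptprc. H2-Ab1 was carried by 24 aged and 5 young wells and H2-Eb1 by 11 and 1. After thinning, Cd74 had a count in 82.1% of aged wells (75.1% to 87.7%) and 20.8% of young wells (14.7% to 28.05%), against 97.4% and 57.3% before. Ptprc, which encodes CD45, had 30 aged counts and 319 young counts. Macrophage markers had medians of 3.31 (aged S1) and 2.77 (aged S2) over young S1, and of -3.09 and -2.06 over young S2.

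**Figure D2:**
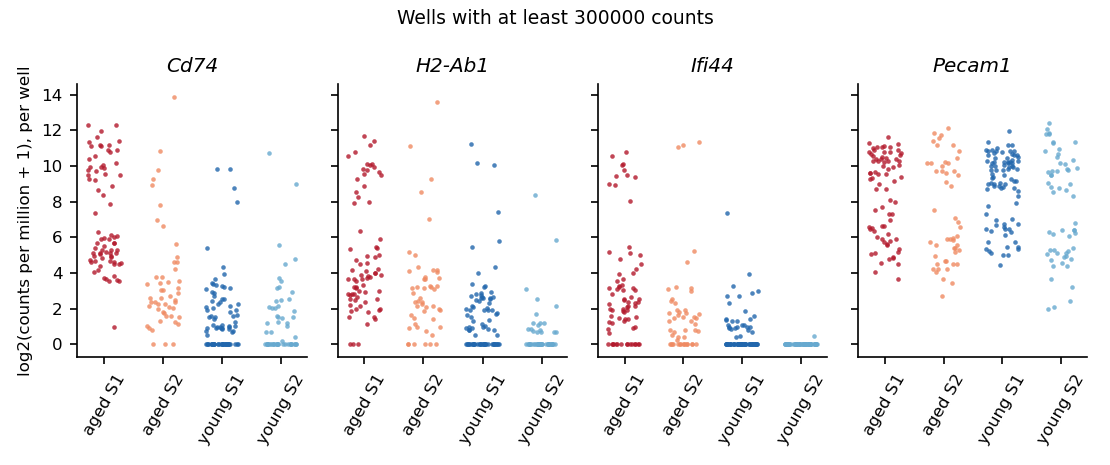
Level of single genes (log2 of CPM plus 1) in each well with at least 300000 counts, 1 point per well, by plate. Cd74 is carried by 32 wells on aged S1, 7 on aged S2, 4 on young S1 and 2 on young S2, and most other wells lie in a band of low values.

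MHC class I genes, which present peptides to CD8 T cells, went both ways as a list, and 3 of them passed the rule of size. B2m, the light chain shared by class I molecules, stood at 9495 CPM in the aged pool and 6081 in the young pool (log2 0.64, 0.26 to 1.07), and H2-K1, a classical heavy chain, at 1803 and 1111 (0.70, 0.23 to 1.33). Those past the rule were H2-Q7 (log2 2.09), H2-Q6 (2.03) and H2-T22 (1.85), all nonclassical heavy chains. Of 21 measured members, 7 were higher and 3 lower in all 4 combinations, with a median of 0.64 (percentile 99.99). The median was 0.64 within S1 plates and -0.01 within S2 plates, and -0.15 without aged S1. The class I heavy chains are close paralogs, and how reads shared between them were counted is not stated, so the split between H2-Q6, H2-Q7, H2-T22 and H2-K1 is uncertain.

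The type I interferon response, the antiviral program, had a median log2 ratio of 1.37 over 22 measured members, of which 10 were higher in the aged pool in all 4 combinations, 0 were lower and 5 passed the rule of size (percentile 100.0). Besides Ifi44 and Ifih1, these were Rtp4, a chaperone induced by interferon, at 256 and 46.2 CPM (2.44), Ifit3, an interferon-induced protein with tetratricopeptide repeats, at 174.09 and 44.3 (1.95), and Trim30a at 134.7 and 41.8 (1.66). Ifit3 and Ifit3b are near copies, and the share of reads between them is uncertain. Rtp4 was carried by 31 aged and 9 young wells. The interferon gamma response had a median of 0.78 over 21 members, with 8 higher and 1 lower in all 4 combinations (percentile 99.8). Irgm2, an immunity-related GTPase, passed the rule at 82.8 and 13.3 CPM (2.55), but it overlaps Igtp on the genome and the split of reads between them is uncertain. Irf1, an early interferon gamma target, stood at 78.5 and 66.6 CPM (0.23).

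Both interferon medians rested on the aged S1 plate. Within S1 plates they were 2.86 (type I) and 1.29 (gamma), and within S2 plates 0.04 and 0.02. Without aged S1 they were -0.12 and -0.06, and at most 2.42 (without young S2) and 1.33 (without aged S2). Pairs of plates that mix the ages gave medians above 0 too: aged S1 and young S2 over the other plates gave 1.35 (type I) and 0.69 (gamma), and the S1 over the S2 plates 0.79 and 0.88. The list of interferon receptors and kinases had a median of -0.29 over 7 members (percentile 32.3), with 0 higher and 0 lower in all 4 combinations. Within S1 plates it was -0.09 and within S2 plates -0.80. Without 1 plate it ran from -0.73 (aged S1) to 0.25 (aged S2). For thinned wells it was 0.03, and without wells with a count of Ptprc -0.96. Ifngr1, the chain that binds interferon gamma, stood at 117.1 CPM in the aged pool and 181.1 in the young pool (-0.62, -2.65 to 1.17), Ifngr2 at 53.6 and 49.6 (0.11), and Jak1, their kinase, at 254.6 and 216 (0.24).

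**Figure D3:**
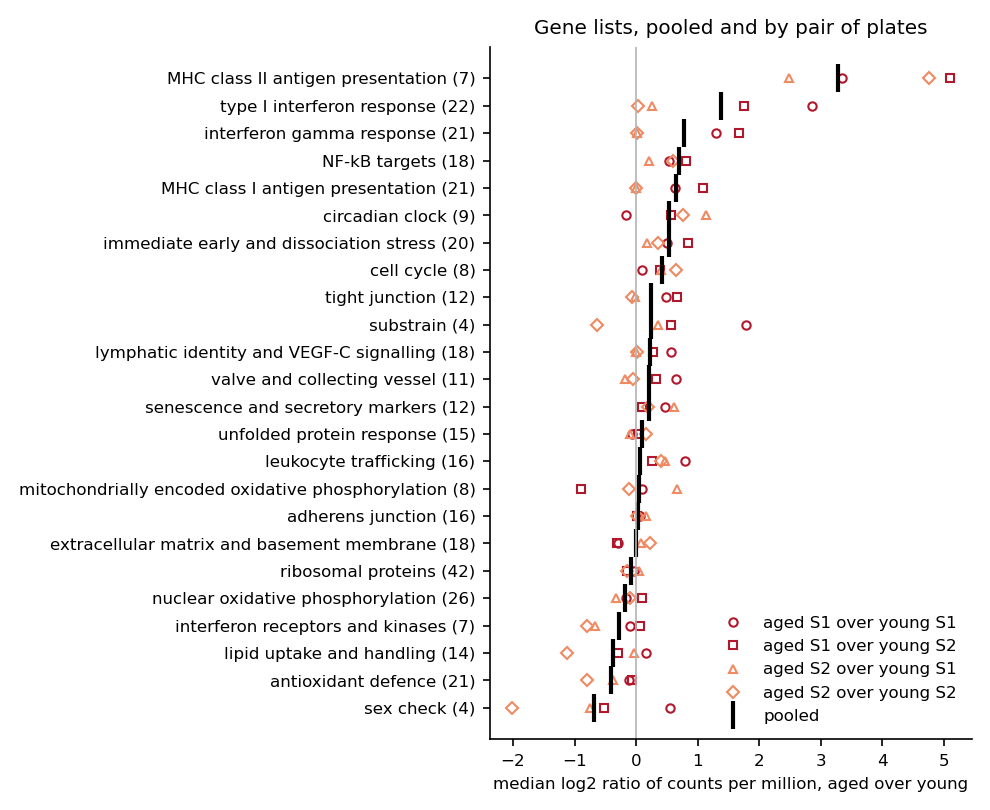
Median log2 ratio, aged over young, of the measured members of each gene list (number in brackets), pooled and by each pair of plates. MHC class II lies at 3.29 pooled, 3.35 within S1 and 4.76 within S2, while the type I interferon list lies at 1.37, 2.86 and 0.04.

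Junction genes differed little as groups. Cdh5, the VE-cadherin that holds endothelial cells together, stood at 383 CPM in the aged pool and 286 in the young pool (log2 0.42, 0.33 to 0.48), and Ptprb, its phosphatase, at 1205 and 1179 (0.03). Of 16 measured adherens junction genes, 3 were higher and 2 lower in all 4 combinations, with a median of 0.02 (percentile 69.4; 0.06 within S1 and 0.02 within S2), which was -0.21 with wells weighted equally, -0.17 with thinned wells, -0.01 without aged S2 and 0.25 without young S2. Cldn5, the main claudin of brain endothelium, stood at 101.8 and 41.3 (1.28, 0.93 to 1.56), but 1 well held 25.5% of its aged counts, which is above the limit of the rule. Jam2, a junctional adhesion molecule, stood at 414 and 355 (0.22). Of 12 measured tight junction genes, 3 were higher and 1 lower, with a median of 0.24 (percentile 79.2; 0.48 within S1 and -0.06 within S2), which was 0.69 without aged S2, 0.43 without young S1 and 0.05 without aged S1.

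Genes of lymphatic identity and VEGF-C signalling, 18 measured, had a median of 0.23 (percentile 88.4; 0.56 within S1 and 0.02 within S2), with 3 higher and 1 lower in all 4 combinations. Without 1 plate it ran from 0.10 (aged S1) to 0.44 (aged S2). Nrp2, the co-receptor of VEGF-C, stood at 477 CPM in the aged pool and 430.2 in the young pool (0.15), and Flt4, the receptor VEGFR-3, at 87.6 and 55.7 (0.64, -1.43 to 3.46). The valve and collecting vessel list, 11 measured, had a median of 0.20 (percentile 76.1; 0.65 and -0.05), with 1 higher and 0 lower, which was 0.34 without young S1, 0.08 with thinned wells and 0.09 with wells weighted equally. Klf2, the transcription factor induced by flow, stood at 1148 and 1043 (0.14). Leukocyte trafficking genes, 16 measured, had a median of 0.07 (percentile 66.98; 0.80 within S1 and 0.40 within S2), with 5 higher and 0 lower, and -0.13 without aged S1 and 0.91 without young S2. Icam2, an adhesion molecule for leukocytes, stood at 623 and 723 (-0.21). Vcam1, another, chosen after its values were seen, stood at 334.8 and 163.2 (1.03, 0.85 to 1.25).

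The lists of stress genes and NF-kB targets had medians above 0, with 1 gene past the rule of size. This was Hspa1a, the inducible HSP70 chaperone, which stood at 187.96 CPM in the aged pool and 75.02 in the young pool (1.31, 0.55 to 1.91), with reads that its copy Hspa1b can share. Of 20 immediate early and dissociation stress genes, which also respond to tissue digestion, 11 were higher and 2 lower in all 4 combinations, with a median of 0.53 (percentile 99.99; 0.49 within S1 and 0.35 within S2) and 0.15 without aged S1. Of 18 NF-kB targets, 9 were higher and 0 lower, with a median of 0.70 (percentile 98.4; 0.54 and 0.60), which was 0.33 without aged S1 and 0.35 without young S2. Nfkbia, the NF-kB inhibitor and the most highly expressed of them, stood at 1487 and 1503 (-0.02). The unfolded protein response, 15 measured, had 4 higher and 6 lower, with a median of 0.09 (percentile 73.02; -0.07 and 0.16) and -0.20 (young S2) to 0.16 (young S1) without 1 plate. Hspa5, the chaperone BiP, stood at 767 and 721 (0.09).

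Lipid and antioxidant genes included some of the lower ones. Cd36, a fatty acid transporter of capillaries, stood at 28.4 CPM in the aged pool and 134.8 in the young pool (log2 -2.21, -2.73 to -1.80), and was carried by 4 aged and 28 young wells. Scarb1, the HDL receptor, stood at 95.2 and 219 (-1.20, -2.06 to -0.34). Of 14 lipid genes, 2 were higher and 6 lower in all 4 combinations, with a median of -0.37 (percentile 10.7; 0.17 within S1 and -1.13 within S2), which was 1.04 without young S2, -1.16 without aged S1 and -0.85 without young S1. Nqo1, a quinone reductase of the NRF2 program, stood at 20.1 and 63.7 (-1.61, -1.92 to -1.39). Of 21 antioxidant genes, 4 were higher and 7 lower, with a median of -0.40 (percentile 1.29; -0.11 within S1 and -0.80 within S2), which was -0.68 without aged S1, -0.16 without aged S2 and -0.20 without young S2. Hhex, a homeobox transcription factor of vessels, at 18.2 and 110.6 (-2.54), and Aqp1, a water channel, at 170.99 and 458.3 (-1.42), were also lower and were named after their values were seen.

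Energy and translation genes had list medians of -0.18 to 0.05. Of 26 nuclear genes of oxidative phosphorylation, 2 were higher and 6 lower in all 4 combinations, with a median of -0.18 (percentile 13.4; -0.16 within S1 and -0.11 within S2) and -0.03 to -0.30 without 1 plate. Cox4i1, of cytochrome oxidase, stood at 1694 and 1695 CPM (0.00). The 8 measured genes encoded in mitochondria had a median of 0.05 (percentile 80.04; 0.09 and -0.12), with 1 higher and 0 lower, which without 1 plate was 0.33 (aged S1), -0.47 (aged S2), -0.48 (young S1) or 0.48 (young S2). Their most abundant member, mt-Cytb, stood at 3622 and 3453 (0.07). Of 42 ribosomal protein genes, which share reads with processed pseudogenes, 0 were higher and 7 lower, with a median of -0.08 (percentile 65.2; -0.03 and -0.15) and 0.01 without young S2. Rps14 stood at 4382 and 4988 (-0.19).

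Markers of other cell classes lay unevenly over the plates. Acta2, the smooth muscle actin, stood at 634 CPM in the aged pool and 66.6 in the young pool (3.23, 1.01 to 4.24). The 9 measured mural markers had a median of 3.23 (percentile 100.0; 1.62 within S1 and 4.43 within S2), with 6 higher and 1 lower, but 0.09 without aged S2, and 7 aged wells and 1 young well carried 3 or more of them. Fibroblast markers (8 measured, median -2.01, percentile 0, 0.01 and -2.62), macrophage markers (9 measured, -1.34, percentile 0.0400, 3.31 and -2.06) and glial or neuronal markers (6 measured, -2.27, percentile 0, 0.31 and -2.73) were lower in the aged pool. Without young S2 their medians were 1.15, 3.55 and 4.75. The lowest without 1 plate were -3.23 (without aged S2), -2.42 (without young S1) and -3.84 (without aged S2). Over the other settings fibroblast markers ran from -3.70 (wells with at least 300000 counts) to -0.01 (without the 5% of wells with most genes). Macrophage markers ran from -2.89 (without well A7 of aged S2) to -0.76 (wells weighted equally), and glial or neuronal markers from -2.28 to 0.62. Dcn, the fibroblast proteoglycan, stood at 317 and 713 CPM (-1.17), and Fcer1g, a receptor subunit of myeloid cells, at 122.2 and 181.6 (-0.57). Wells with 3 or more markers numbered 2 for fibroblasts (young S2), 3 for macrophages (2 aged, 1 young) and 6 for glia or neurons (3 and 3). Lymphatic markers, 7 measured, had a median of 0.15 (percentile 65.4; 1.89 and -0.02), which was -0.63 without aged S1 and 3.01 without young S2. Blood endothelial markers, 9 measured, had -0.04 (percentile 56.2; 0.05 and 0.07), which was -0.39 without aged S1, 0.16 without young S1 and -0.35 without young S2.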

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

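Alternatives were fixed beforehand, except wells with at least 300000 counts alone and the removal of wells carrying markers of another class or of well A7 of aged S2, which were chosen after seeing the data. No paired analysis was possible because the labels name no mouse per well, so S1 and S2 are plates of 1 pool and no result here comes from a test. The 247 genes past the rule of size became 450 (39.3% higher in aged) with plates of the same number only, 34 (70.6%) at an expression minimum of 200, 78 at 4-fold and 422 (59.7%) with no limit on a single well, and thinning gave 62.98% higher. Leaving out 1 plate gave 399 to 728 genes, 16.6% to 81.95% higher. With fewer combinations to satisfy, more genes can pass. For genes higher in the age that loses a plate, each remaining well holds a larger share of the counts. The limit on a single well can then be harder to meet. The sign held for the 12 higher and 12 lower genes named by rank, which were picked for having 1 sign on all plates, but of those higher only 1 still passed without aged S1, 6 without the 5% of wells with most genes and 7 without wells with a count of Ptprc, and of those lower 0 passed without young S1. Leaving out aged S1 reversed the medians of interferon gamma (-0.0614, and 1.33 at most) and type I interferon (-0.12, at most 2.42). Without 1 plate the other medians ran from -0.15 to 0.86 (MHC class I), 2.69 to 4.91 (MHC class II), -0.0096 to 0.25 (adherens junction) and 0.0467 to 0.69 (tight junction). The adherens median was also -0.21 with wells weighted equally and -0.17 when thinned. In each case but the rule's own construction, the cause was not tested. No cluster was lymphatic-like under any of 9 other settings. Top genes by fold rank a cluster against other wells, so the call could also fail if all wells were lymphatic. It therefore says nothing on the identity of the wells. Of the other list medians, 366 values moved by up to the standard deviation over plate combinations and 32 by more, and of single genes 1042 and 83, with 0 past the rule reversed. Leaving out 1 plate could not reverse those, because the rule asks for 1 sign in all plate combinations. Using all kept wells, no well filter or other clusterings for the ratios changed nothing, because each kept the same 384 wells, and so says nothing about stability. Depth limits any gene carried by few wells, since wells under 100000 counts hold mostly spill by the upper estimate.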

Other observations

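Lists outside the main comparison gave these values. Of 12 measured senescence and secretory genes, 3 were higher in the aged pool and 1 lower in all 4 plate combinations, with a median log2 ratio of 0.20 (percentile 84.1, 0.47 within S1 plates and 0.19 within S2 plates), which was 0.66 without young S2, 0.13 without young S1 and 0.08 without wells with a count of Ptprc. Igfbp5, a binding protein of insulin-like growth factors, stood at 1265 CPM (scaled counts) in the aged pool and 919.9 in the young pool (0.46), and the cell cycle inhibitor Cdkn1a, chosen after its values were seen, at 417.5 and 425.2 (-0.03). Extracellular matrix genes, 18 measured, had a median of 0.00 (percentile 49.6, -0.29 and 0.22), with 4 higher and 3 lower, and -0.21 without aged S2 to 0.34 without young S1, -0.10 with wells weighted equally and -0.14 with no minimum for members. Sparc, a matrix glycoprotein made by vessels, was lower on both aged plates, at 1102.4 against 1824 (-0.73, -0.87 to -0.58). Of 8 measured cell cycle genes, 1 was higher and 1 lower (median 0.42, percentile 81.35, 0.09 and 0.65), with -0.01 when the 5% of wells with most genes were left out and 1.27 without young S1. Pcna, the replication clamp, stood at 82.3 and 32.5 (1.32, -0.37 to 2.08). Of 9 measured clock genes, 2 were higher and 0 lower (median 0.54, percentile 74.7, -0.16 and 0.76, and -0.04 without aged S2 to 0.85 without aged S1), and the most highly expressed, Arntl, stood at 51.01 and 39.8 (0.35).

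Further markers and checks follow. T or NK cell markers had 2 measured members (median -2.01, 0.36 within S1 and -2.55 within S2, and without 1 plate -4.36 (aged S1) to -0.41 (young S2), or 0.37 without wells of another class), and 93.8% of the young counts of Cd4 lay in 1 well. Erythroid markers had 2 (median -2.99, -3.48 and -1.63), with Hba-a1 at 0.338 and 12.4 CPM. B cell, neutrophil, mast cell, and bone or cartilage markers had 0 measured members, and 0 of 269 deep wells carried 3 or more of any of these. Of genes known to differ between the substrains, 4 were measured (median 0.24, percentile 59.6, 1.79 within S1 and -0.64 within S2, and -0.06 without aged S1, 1.10 without aged S2, -0.41 without young S1 and 1.27 without young S2, or -0.45 without wells with a count of Ptprc). Nnt, which carries a deletion in C57BL/6J, stood at 10.2 and 17.7 (-0.75, -4.70 to 1.33) with 77.8% of its young counts in 1 well. A deletion of inner exons need not lower counts taken near the polyA tail, so these values say nothing on the substrain. Of the sex genes, 4 were measured (median -0.68, percentile 16.95, 0.54 and -2.02, and -1.48 without aged S1 to 0.04 without young S2). Xist, which is expressed from the inactive X of females, had 8 aged and 13 young counts, and Ddx3y, on the Y chromosome, stood at 155.04 and 115.98 CPM (0.42).

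The tests in the rest of this part, all 7, were chosen after the results were seen. The wells sorted as lymphatic had little lymphatic RNA. That Prox1 was merely left uncounted in wells otherwise lymphatic runs against the data, since 2.23% of deep wells carried 3 or more lymphatic markers. A candidate explanation is blood endothelium inside the sort gate, since 81.04% carried 3 or more blood endothelial markers, although lymphatic vessels also express some of these genes. Lyve1 protein at the surface with low RNA, or staining without specificity, stays open and was not tested.

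MHC class II genes were higher in the aged pool. Macrophage markers were higher too on the aged plates over young S1 (medians of 3.31 and 2.77), though not over young S2, and well A7 of aged S2 had macrophage markers. Immune cells of the classes with a marker list still run against the data as the whole cause. In the 212 deep wells with 3 or more blood endothelial markers and no other class, the class II median was 2.98 (3.83 within S1 plates and 5.39 within S2 plates). Macrophage markers had a median log2 ratio of -0.16 there, and 2.06 CPM in the aged pool. Those wells were picked for carrying no immune class, so the low macrophage markers add no support of their own. No marker list covered dendritic cells, and doublets were not called. Such cells sharing a well with endothelium are therefore not excluded. On the S1 plates, spill can also make a well carry a blood endothelial marker. A cause in 1 plate number alone also runs against the data, since the smaller of the class II medians within S1 and within S2 plates was 3.35. The S2 median was 4.13 without well A7, which held 53.5% of the aged S2 counts of H2-Eb1. It also rests on low levels on young S2, such as 7.86 CPM for H2-Ab1 and 0.0219 CPM for H2-Eb1. A few wells with very high counts cannot be told apart from a broad difference, since members were carried by a median of 11 aged wells (2 young), between bounds of 5 and 20 set afterwards, and age and substrain stay open, untested.

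Interferon response genes of both lists together, 43 measured members, had a median of 1.04. That median rested on the aged S1 plate: it was 1.99 within S1 plates and 0.0246 within S2 plates. Aged S1 over young S2 still had medians of 1.75 (type I) and 1.68 (gamma). Aged S2 over young S1 had only 0.26 and 0.01. Of the members, 22 were above 0 within both S1 and S2 plates, and 1 was below 0 in both. A few wells with very high counts cannot be told apart from a broad difference here either, since members were carried by a median of 13 aged wells (5 young). Age and substrain stay open here too, untested, and S1 and S2 may differ in sort, mice sampled or library preparation, none of which the labels give.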
